A study of Mus musculus with 23 samples.

How the data were processed

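RNA of the prefrontal cortex of male Balb/c mice was measured 18, 72 and 192 h after a subcutaneous injection of CT-26.WT cells, a mouse colon carcinoma line, or of PBS alone. On each array, printed in house with oligonucleotides, cortex RNA after tumour cells and cortex RNA after PBS were hybridised together, 1 in Cy3 and the other in Cy5. The deposit holds 23 arrays of 11 biological replicates on 5 print layouts, with 10080 spots per array and 3 scanner files per array. Per the labels, replicates 1 and 2 at 72 h and replicates 1 and 2 at 192 h were poly(A) RNA and the others total RNA. The labels number the 18 h replicates 3, 4 and 5.

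Per the file headers, each scanner file gives for both channels a spot intensity with the local background already subtracted by the authors' software and the background intensity beside it, on a linear scale. The image software and its settings are not stated. The authors' own processed table gives 1 score per spot and array, a log ratio of tumour over PBS centred near 0, with array medians from -0.00574 to 0.00808. The normalisation behind that deposited score is not stated. Its log base could not be settled from the values, since its slope on the log2 ratios of the scanner files lay between 0.419 and 0.603 on the arrays kept and between 0.357 and 0.665 on those left out, so it served for signs and tests only. Values per spot are arbitrary units of brightness, and the number of arrays limits the precision. Which scanner channel held which dye is not stated. Channel A was taken as Cy3 and channel B as Cy5, because the deposited scores then follow the dyes of the labels (correlation across spots with the scanner ratios, 0.636 to 0.919 on the arrays kept). Were the channels the other way round, every direction given here would turn.

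Spots marked B (areas from 31 to 49 pixels) or without signal (marks X, Y and Z) were left out. The log2 ratio of the background-subtracted intensities was normalised in each scanner file by a global loess against mean intensity (limma loessFit, span 0.3, 4 iterations). The ratio was turned to tumour over PBS and averaged over the 3 files. Spots of 1 GenBank entry, called a probe here, were averaged. The arrays of 1 replicate were then averaged, and a replicate measured as a dye swap needed both orientations. Probe names came from the deposited platform tables. No genome build is named there, and symbols were updated by gene identifier with a reference table of assembly GRCm38.p6, used for names alone. Of the 10080 spots, 9074 (9066 on 2 layouts) had 1 symbol, which gave 8726 symbols.

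7 arrays were left out because their intensities did not bear out their probe names. Over the 23 arrays, the mean intensity of each probe was compared by Spearman's rho with that on arrays of other layouts on which the 77 fixed ribosomal and oxidative phosphorylation genes lay at or above the 75th percentile of intensity. The mean rho was 0.00857 to 0.0495 on the 5 arrays of layout 1, 0.0304 on the 1 array of layout 2 and 0.0423 on 1 array of layout 5, against 0.188 to 0.503 on the 16 arrays kept. Against arrays of its own layout, the kept array of 72 h replicate 3 had a mean rho of 0.062, also under that size, where the other kept arrays of layout 5 had 0.206 to 0.436. That array is the whole of the replicate, and the alternatives include runs without it. The 6 arrays of layouts 1 and 2 had a mean rho of 0.369 with one another. The array left out of layout 5 had a mean rho of 0.0793 within its layout, above that of its kept dye-swap partner. The pair had a rho of 0.0696 with each other, which does not show whose names are wrong. The limit of 0.1 was chosen after these values were seen and before any test of tumour against PBS. It removed replicates 1 and 2 at 72 h in full, 1 array of replicate 3 at 72 h and 1 array of replicate 1 at 192 h. All 23 arrays with the names as deposited were run as an alternative. Of the 9 replicates kept, 6 were dye swaps and 3 had 1 orientation (72 h replicate 3 and 192 h replicate 1 with tumour RNA in Cy5, 192 h replicate 2 with tumour RNA in Cy3).

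Each probe with at least 2 replicates at a time was fitted by least squares with a mean per time and the dye orientation of the replicate (0 for a swap, 1 or -1 otherwise), with the spread shared over probes by limma 3.58.1 (squeezeVar) under R 4.3.3. On probes without missing values the results equalled those of lmFit, contrasts.fit and eBayes. This is called the limma test below. p values were adjusted by Benjamini and Hochberg over all probes of a comparison, with a threshold of 0.05. Comparisons were each time against 0, the mean of the 3 times against 0, and the differences between times (F test and the 3 pairwise differences). Errors are standard errors of the fit. The dye coefficient rests on the 3 replicates of 1 orientation alone. Where replicates 1 and 2 at 192 h both have a value, it rests mostly on their difference. That pair is of poly(A) RNA, and a difference between its samples cannot be told apart from a dye effect. Through 72 h replicate 3, of total RNA, this difference also enters the fitted ratios at 72 h. A fitted ratio is the value after this covariate, so it can lie outside all replicate values of its time. 24 gene lists were fixed, and each with at least 4 measured genes, 1 probe per gene, was tested at each time with limma's camera (preset correlation 0.01), adjusted over all lists and times. A second camera test used a correlation estimated from members measured in every replicate (0 where the estimate was below 0, and the preset value with fewer than 2 such members). The directional fry test was run on lists with at least 4 such members. A replicate median of a list is taken without the dye covariate over all members with a value in that replicate. Its genes can therefore differ from those tested at the time.

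The comparisons, the gene lists, the alternatives and the rule for named genes were written before the data were examined. The rule took, per time and for the mean, up to 10 genes higher and 10 lower among those past the threshold with 1 sign in every replicate, then the smallest unadjusted p up to 10 genes in all. It added up to 3 members of any list that passed or held a gene past the threshold, the 5 smallest p of the F test, and Fos, Fkbp5, Gfap, Serpina3n, Mbp, Ttr, Hbb-b1 and Hba-a1 where measured. Clone names were skipped. Other list members named in the text were chosen after their values were seen, as those with small p in their list. Also chosen after the files were seen were the treatment of the spot marks, the need for both orientations and 8 added alternatives. The third file of 1 array of 192 h replicate 3, whose log ratios correlated at as little as 0.102 with those of another file of the array, was kept in the values and left out in an alternative. The counts of genes past the threshold at each time had been seen in a first fit before the tests on simulated data were run and the predictions of the closing section were written.

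On simulated ratios with the real pattern of missing values, 200 genes were changed at a time. The simulated noise was normal and independent, and each probe had the same spread in every replicate. The real replicates had standard deviations from 0.177 to 0.489, so the real shares found may differ from those below. A log2 ratio of 1 was found for 86.0% of them at 18 h, 72.5% at 72 h and 80.5% at 192 h. A log2 ratio of 0.5 was found for 0% at 18 h, 0% at 72 h and 0.5% at 192 h. False calls at a log2 ratio of 1 were 10 of 182 calls at 18 h, 7 of 152 at 72 h and 7 of 168 at 192 h. At a log2 ratio of 2 they were 12 of 212, 22 of 220 and 8 of 208.

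Alternatives changed the background handling, the loess, the spot marks, the scanner file, scaling between arrays, a filter on dim spots, the dye covariate, the unit of the fit (arrays or genes), the RNA type, the print layout, array weights, the deposited scores, the replicate number as a block, and each replicate in turn. With all arrays in the fit, the arrays kept were fitted singly with the replicate as a random block.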

Results

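The series measured transcript abundance in mouse prefrontal cortex on 2-colour arrays after subcutaneous injection of 1000000 CT-26.WT colon carcinoma cells or of PBS alone. The value of a gene is the log2 ratio of tumour over PBS within an array. 16 arrays entered the comparisons, from 3 replicates at 18 h (6 arrays), 2 at 72 h (3 arrays) and 4 at 192 h (7 arrays). The scanner files of these arrays held 1821 to 8638 usable spots each. The median spot signal, background included, was 1.73 to 4.01 times the local background. In all, 7364 probes for 7174 gene symbols were tested at 1 time or more, and 769 had a value in every replicate. The median standard error of a log2 ratio was 0.16 at 18 h, 0.19 at 72 h and 0.15 at 192 h. No gene positions are given, because the platform names no genome build.

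The comparison at 18 h asks which cortical transcripts differed soon after the tumour cells were injected. The smallest p belonged to Armc1, an armadillo repeat gene, at a log2 ratio of -0.83 ± 0.12 (adjusted p = 0.108), lower in 3 of 3 replicates. Atp6ap2 and Atp6v1a, subunits of the vacuolar proton pump that acidifies lysosomes and synaptic vesicles, stood at -1.0 ± 0.18 (adjusted p = 0.449) and -0.75 ± 0.16 (adjusted p = 0.759), each lower in 2 of 2 replicates. Chst13, a chondroitin sulfotransferase, was at -0.62 ± 0.11 (adjusted p = 0.449) and lower in 3 of 3. Cplx1, a complexin that binds the assembled release complex at presynaptic terminals, was at -0.50 ± 0.12 and lower in 3 of 3 replicates. Tmem68 was at -0.95 ± 0.18 (adjusted p = 0.663), Cnn3, an actin-binding calponin, at -1.15 ± 0.25, and Trim34a at -0.70 ± 0.18, each lower in 2 of 2. Mcm10, a DNA replication factor, was at 0.87 ± 0.17 and higher in 2 of 2 replicates. Tmem222 was at 0.82 ± 0.19 and higher in 2 of 2, but at -0.16 with a loess inside each sub-grid. The adjusted p of Cplx1, Cnn3, Trim34a, Mcm10 and Tmem222 was 0.759. The limma test called 0 of 5733 probes at 18 h, with 342 at an unadjusted p under 0.05. That share is little above the 0.05 that chance alone gives where all replicates vary alike. With the print layout as a random block 1 probe passed, Armc1, at an adjusted p of 0.0316. The correlation estimated for that block was below 0 (-0.0818), and the 18 h replicates all share a layout. A negative correlation makes their standard errors smaller (0.10 for Armc1), so this pass adds no support.

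Among the fixed gene lists at 18 h, the synaptic vesicle and release machinery had the smallest p. Of its 12 measured genes 7 were lower and 5 higher, with a median log2 ratio of -0.18 (camera adjusted p = 0.267). Its lowest members by p were Cplx1 and Snap25, a membrane fusion protein of the release complex, at -0.65 ± 0.19 and lower in 3 of 3 replicates. Syt4, a synaptotagmin, was at -0.72 ± 0.28 and lower in 2 of 3, with -1.31 for Snap25 and -1.86 for Syt4 in replicate 5, and Syn2, a synapsin, at -0.21 ± 0.13 and lower in 3 of 3. 2 members passed when adjusted over the list alone and 0 when adjusted over all probes. The median of the list was 0.03 in replicate 3, -0.24 in replicate 4 and -0.31 in replicate 5. The adjusted p was 0.887 with an estimated correlation, which rested on 4 members. The list passed camera, lower, in 3 alternatives, with adjusted p of 0.00478 (the third scanner file alone), 0.00197 (all kept arrays fitted singly) and 0.00521 (1 dye orientation enough). These 3 used the preset correlation of 0.01, whereas the estimate for the list was 0.555. They are therefore no independent support.

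**Figure D1:**
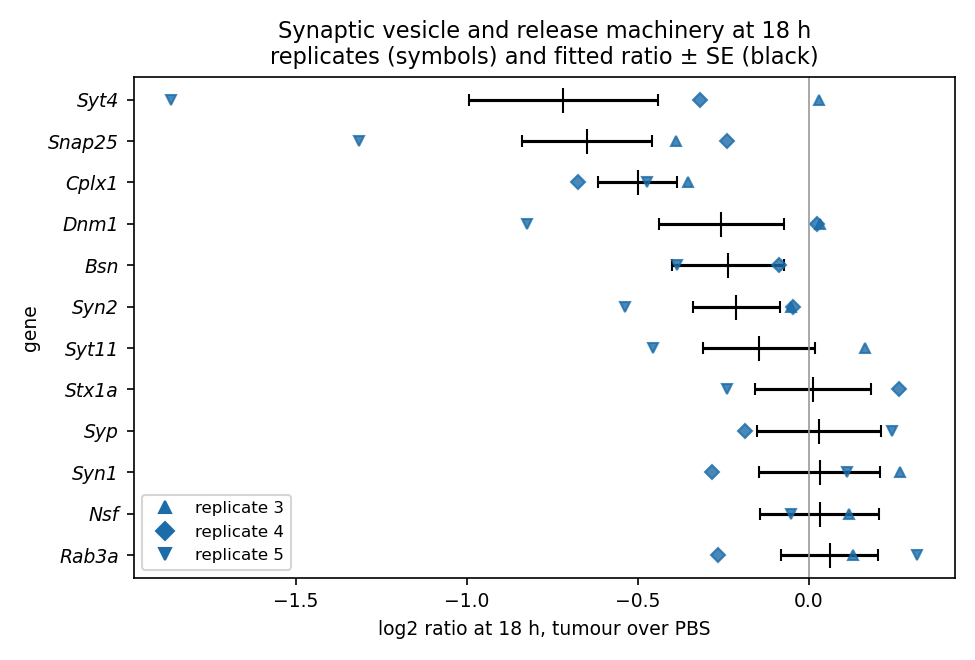
Log2 ratio of tumour over PBS at 18 h for each measured gene of the synaptic vesicle and release machinery list, with points for the replicates and bars for the estimate with its standard error. Of the 12 genes 7 lie below 0 and 5 above, and Cplx1 and Snap25 lie below 0 in 3 of 3 replicates.

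Inhibitory neuron markers at 18 h were lower in 10 of 10 measured genes, by small amounts, with a median of -0.09 (adjusted p = 0.527) that stayed below 0 in each of 8 scaling alternatives. The replicate medians were 0.13, -0.01 and -0.43, the last in replicate 5. The member with the smallest p was Kcnc1, a potassium channel of fast-spiking interneurons, at -0.31 ± 0.13, and Gad1, which makes GABA, was at -0.47 ± 0.23 with 1 of 2 replicates lower. Choroid plexus and meninges markers were higher in 5 of 6 genes, with a median of 0.11 (adjusted p = 0.527) and with Igf2, a growth factor of the meninges, at 0.53 ± 0.17 and higher in 3 of 3 replicates. Striatum markers were lower in 5 of 5 genes, with a median of -0.05 (adjusted p = 0.645). Microglia and macrophage markers were lower in 5 of 6, with a median of -0.13 (adjusted p = 0.816). Heat shock and endoplasmic reticulum stress genes had a median of -0.06 (7 of 12 lower, adjusted p = 0.645), with Dnaja1, a co-chaperone, at -0.40 ± 0.14 and lower in 3 of 3.

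Excitatory neuron markers had a median of 0.12 (7 of 11 higher, adjusted p = 0.582), which turned below 0 with each scanner file alone. Immediate early genes, which neurons switch on with activity, went both ways at 18 h. Arc, a synaptic plasticity gene, was at 1.21 ± 0.36 and higher in 3 of 3 replicates (0.02, 2.64 and 0.96), and Fosb at -0.44 ± 0.19 and lower in 2 of 2. Their median was -0.02 and their mean 0.08 over 11 genes (adjusted p = 0.948), with the median above 0 for the first scanner file alone and for the deposited scores. Cytokine and endothelial inflammation genes had 12 of 19 higher (median 0.04, adjusted p = 0.816), below 0 in 5 of 8 scaling alternatives. Saa3, an acute phase protein, was at 1.52 ± 0.49 and higher in 2 of 2 (0.21 and 2.83). Oxidative phosphorylation genes were lower in 32 of 54 (median -0.05, adjusted p = 0.645), with Cox8b at -0.68 ± 0.16 and Atp5e at 1.26 ± 0.33; the median turned above 0 without loess and with the deposited scores. Ribosomal protein genes were lower in 11 of 17 (median -0.05, adjusted p = 0.645), above 0 without loess. Circadian clock genes were higher in 7 of 9 (median 0.05, adjusted p = 0.645), below 0 with the second scanner file alone, with Nfil3, a clock-linked repressor, at 0.68 ± 0.25 and higher in 2 of 2. Endothelial markers had a median of -0.01 and a mean of 0.03 over 5 genes (adjusted p = 0.861). Astrocyte markers had a median of 0.01, a mean of -0.05 and a test direction of lower (adjusted p = 0.865). Their member Slc4a4, a bicarbonate transporter, was at -0.41 ± 0.12, lower in 3 of 3, and passed when adjusted over the list alone. In all, 0 of 23 lists passed at 18 h by camera and 3 had an unadjusted p under 0.05. The sign of the median turned in at least 1 scaling alternative for 16 of the 23. Replicate medians took both signs at 18 h for the cytokine (0.15, -0.15 and 0.06), oxidative phosphorylation (0.07, -0.18 and -0.04), ribosomal (0.03, -0.23 and -0.14), circadian (0.04, 0.20 and -0.12) and heat shock lists (0.07, -0.03 and -0.30).

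At 72 h, with 2 replicates, 65 of 4440 probes had an unadjusted p under 0.05 by the limma test. That is a smaller share than the 0.05 that chance alone gives where all replicates vary alike. The standard deviations of the replicates differed, with 0.26 and 0.23 at 72 h and 0.49 and 0.47 in replicates 1 and 2 at 192 h. Scaling between arrays raised the count to 152 of 4440. The test called 1 of the 4440. It was Spata48, a gene named for spermatogenesis, at a log2 ratio of 3.39 ± 0.22 (adjusted p = 0.0051), higher in 2 of 2 replicates. Its ratio was 0.10 in replicate 3 and 3.39 in replicate 4. On the swapped arrays of replicate 4 it was -0.32 with tumour RNA in Cy5 and 7.10 with tumour RNA in Cy3. The dye covariate takes up replicate 3, so that the estimate is that of replicate 4 alone, and the residual comes from another time. The call ended, with 0 probes past and 60 at an unadjusted p under 0.05, when only probes whose own replicates leave a residual were tested. It ended as well without the dye covariate (1.74, adjusted p = 1.00).

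The other 9 genes with the smallest p at 72 h did not pass. Nr4a2, a nuclear receptor induced early by neuronal activity, was at 1.74 ± 0.35 (adjusted p = 0.851), with replicate values of 0.04 and 2.23. Dapk3, a death-associated kinase, was at -1.0 ± 0.21 and Efhc2 at -1.25 ± 0.24, each lower in 2 of 2 replicates at the same adjusted p. Dbf4, which activates a kinase at replication origins, was at 0.73 ± 0.16 and higher in 2 of 2, and Ttll11, a tubulin polyglutamylase, at 1.08 ± 0.23 and higher in 1 of 2 (adjusted p = 0.851 for both). Tdrd1 (0.78 ± 0.18), Hdac9, a histone deacetylase (0.89 ± 0.20), Map3k6, a stress kinase (0.83 ± 0.20), and Smox, a spermine oxidase (0.74 ± 0.20), were each higher in 2 of 2 at an adjusted p of 0.999. Replicate 4 carried several of these values: replicates 3 and 4 gave 0.02 and 1.15 for Map3k6, 0.29 and 0.95 for Smox, 0.08 and 0.80 for Dbf4, -0.04 and 1.24 for Ttll11, -0.14 and -1.38 for Dapk3, -0.53 and -1.58 for Efhc2, and 0.41 and 0.83 for Hdac9. For Tdrd1 they gave 0.53 and 0.54. The dye covariate puts the fitted ratios of Tdrd1 and Hdac9 above both of their replicate values. For Tdrd1 that covariate rests mostly on 192 h values, -0.59 in replicate 1 and 0.62 in replicate 2. Without replicate 3, which leaves replicate 4 alone at 72 h, Nr4a2 reached 2.23 (adjusted p = 0.016) and Dapk3 -1.38 (adjusted p = 0.0397). Without loess Efhc2 reached -1.52 (adjusted p = 0.0163).

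None of the 20 lists measured at 72 h passed by camera, and 0 had an unadjusted p under 0.05. The synaptic vesicle and release machinery had 8 of 12 genes lower, with a median of -0.09 (adjusted p = 0.527), below 0 in each of the 8 scaling alternatives, and with the vesicle proteins Syp at -0.33 ± 0.20 and Sv2a at -0.29 ± 0.17. Monoamine, opioid and neuropeptide signalling genes were lower in 12 of 14 after the dye covariate (median -0.12, adjusted p = 0.527), above 0 without loess. Before it the medians of this list were 0.04 in replicate 3 (17 genes) and -0.04 in replicate 4 (15 genes). Tacr1, the receptor of substance P, was at -1.50 ± 0.47 and lower in 1 of 2 replicates. Astrocyte markers were lower in 4 of 5 genes (median -0.12, adjusted p = 0.527), with Slc4a4 at -0.37 ± 0.17 and lower in 2 of 2. Epithelial tumour cell markers were higher in 4 of 4 genes (median 0.11, adjusted p = 0.527), with the tight junction gene Cldn4 at 0.39 ± 0.20. Their medians before the dye covariate were 0.10 over 7 genes in replicate 3 and -0.06 over 4 genes in replicate 4. Excitatory neuron markers had a median of -0.13 (6 of 9 lower, adjusted p = 0.821), with -0.18 in replicate 3 and 0.04 in replicate 4. Blood leukocyte markers were higher in 5 of 6 genes after the dye covariate (median 0.12, adjusted p = 0.578), below 0 with the deposited scores, and their replicate medians before it were -0.05 and 0.16. Among immediate early genes 4 of 8 were higher and 1, Nr4a2, passed when adjusted over the list alone. Glucocorticoid-responsive genes had a median just below 0, a mean of 0.07 and a test direction of higher (adjusted p = 0.645), and 1 of 11, Map3k6, passed when adjusted over the list alone. The cell cycle gene Top2a was at 0.44 ± 0.16 and higher in 2 of 2 replicates. The sign of the median turned in at least 1 scaling alternative for 16 of the 20.

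At 192 h 240 of 6465 probes had an unadjusted p under 0.05 by the limma test. That share is smaller than chance alone gives where all replicates vary alike. The test called 1 of the 6465. It was Krtap13, a keratin-associated gene of hair, at 2.23 ± 0.16 (adjusted p = 0.0123), but its replicates had opposite signs, -0.15 in replicate 1 and 4.62 in replicate 2, and replicates 3 and 4 gave no value. With 1 dye orientation in each of these replicates the fit passes through both values and the residual comes from another time. The call ended, with 0 probes past and 206 at an unadjusted p under 0.05, when an own residual was required. It ended as well without the dye covariate (2.23, adjusted p = 0.999).

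Among the other genes with the smallest p at 192 h, Stambpl1, a deubiquitinating enzyme, was at -1.16 ± 0.19 and lower in 2 of 2 replicates (adjusted p = 0.980). It gave -0.71 in replicate 1 and -1.15 in replicate 4, and the fitted ratio lies below both. Myo10, a myosin of filopodia, was at 0.91 ± 0.17, Hsd17b11, a steroid dehydrogenase, at 0.84 ± 0.16, and Dlg5, a scaffold protein of cell junctions, at 0.84 ± 0.16, each higher in 2 of 2 (adjusted p = 0.980). Tecta, a matrix protein of the inner ear, was at 0.62 ± 0.13 and Pcolce, an enhancer of procollagen processing, at 0.60 ± 0.14, each higher in 3 of 3 replicates (adjusted p = 0.980). Nrde2 was at 0.58 ± 0.14 and higher in 4 of 4, Alas1, the first enzyme of haem synthesis, at 0.55 ± 0.14 and higher in 3 of 4, and Rabep2 at 0.92 ± 0.21 and higher in 2 of 2 (adjusted p = 0.999 for the 3). Here too 1 replicate carried several values. In replicates 1 and 2, each of 1 dye orientation, Hsd17b11 gave 1.65 and 0.03, Myo10 1.56 and 0.26, and Dlg5 1.05 and 0.63. For Hsd17b11 and Myo10 the fit passes through both values, as for Krtap13, and the residual behind the error comes from 18 h. Alas1 reached 1.60 and Tecta 1.30 in replicate 1, and Nrde2 1.5 in replicate 2, above the other replicates.

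None of the 23 lists passed at 192 h, and 0 had an unadjusted p under 0.05. Oligodendrocyte and myelin genes were lower in 7 of 9, with a median of -0.13 (adjusted p = 0.527), above 0 without loess and with the third scanner file alone. Before the dye covariate their medians were 0.13, -0.22, 0.01 and -0.06 in replicates 1 to 4, so the replicates did not share a direction. Mag, a myelin glycoprotein, was at -0.21 ± 0.12 and Sox10, a factor of the oligodendrocyte lineage, at -0.19 ± 0.12, each lower in 3 of 4 replicates. Immediate early genes were lower in 10 of 13 (median -0.06) and synaptic vesicle and release genes in 11 of 15 (median -0.07), both at an adjusted p of 0.527 and both above 0 without loess. In replicates 1 to 4 the medians of the immediate early genes were -0.25, 0.18, near 0 and 0.02, with no shared direction, and those of the synaptic list -0.10, -0.09, -0.04 and near 0. Microglia and macrophage markers were higher in 6 of 9 genes (median 0.07, adjusted p = 0.797; replicate medians 0.10, -0.10, 0.20 and 0.10), with C1qc, a complement subunit, at 0.36 ± 0.15 and higher in 3 of 3. Astrocyte markers were higher in 6 of 7 (median 0.08, adjusted p = 0.816), but the replicate medians were 0.15 in replicate 1 and -0.01, -0.01 and -0.02 in the others. Heat shock and endoplasmic reticulum stress genes were higher in 11 of 15 (median 0.06, adjusted p = 0.816). The medians of the microglia and stress lists stayed above 0 in each of the 8 scaling alternatives. Proteasome and ubiquitin genes were higher in 13 of 21 (median 0.03, adjusted p = 0.816) and also kept a median above 0. Interferon response genes were higher in 3 of 5 (median 0.01, adjusted p = 0.923), below 0 in 2 scaling alternatives. Cholesterol biosynthesis genes were higher in 5 of 9 (median 0.02, adjusted p = 0.948), below 0 without background correction. Cell proliferation genes were higher in 3 of 6 (median 0.05, adjusted p = 0.645), below 0 in 2 scaling alternatives. Single members with small p were Htr1b, a serotonin receptor, at -0.69 ± 0.16 (lower in 2 of 2), the proliferation marker Mki67 at 0.45 ± 0.15 (higher in 2 of 3), the interferon-induced Isg15 at 0.37 ± 0.16 (higher in 3 of 3) and the chemokine Cxcl1 at 0.32 ± 0.13 (higher in 2 of 3). Their adjusted p was 0.999 over all probes, and 0 members of any list passed when adjusted over the list alone. The sign of the median turned in at least 1 scaling alternative for 19 of the 23. Replicate medians before the dye covariate also took both signs at 192 h for the stress, proteasome, interferon, cholesterol and proliferation lists.

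Over all times, 0 of 66 camera tests passed, with 3 at an unadjusted p under 0.05. A correlation could be estimated for 9 lists (27 tests), those with at least 2 members measured in every replicate, and the preset one stood in for the others; 0 tests passed, with 1 at an unadjusted p under 0.05. The fry test could be run for 6 lists (18 tests), and 0 passed, with 0 at an unadjusted p under 0.05. 0 list members passed over all probes at any time. Haemoglobin and red cell genes had too few measured members for a test. The medians of the lists lay between -0.18 and 0.12 at 18 h, between -0.14 and 0.12 at 72 h and between -0.13 and 0.12 at 192 h. Median and mean had opposite signs for 4 lists at 18 h, 3 at 72 h and 5 at 192 h. Median and test direction did so for 3, 4 and 5 lists.

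**Figure D2:**
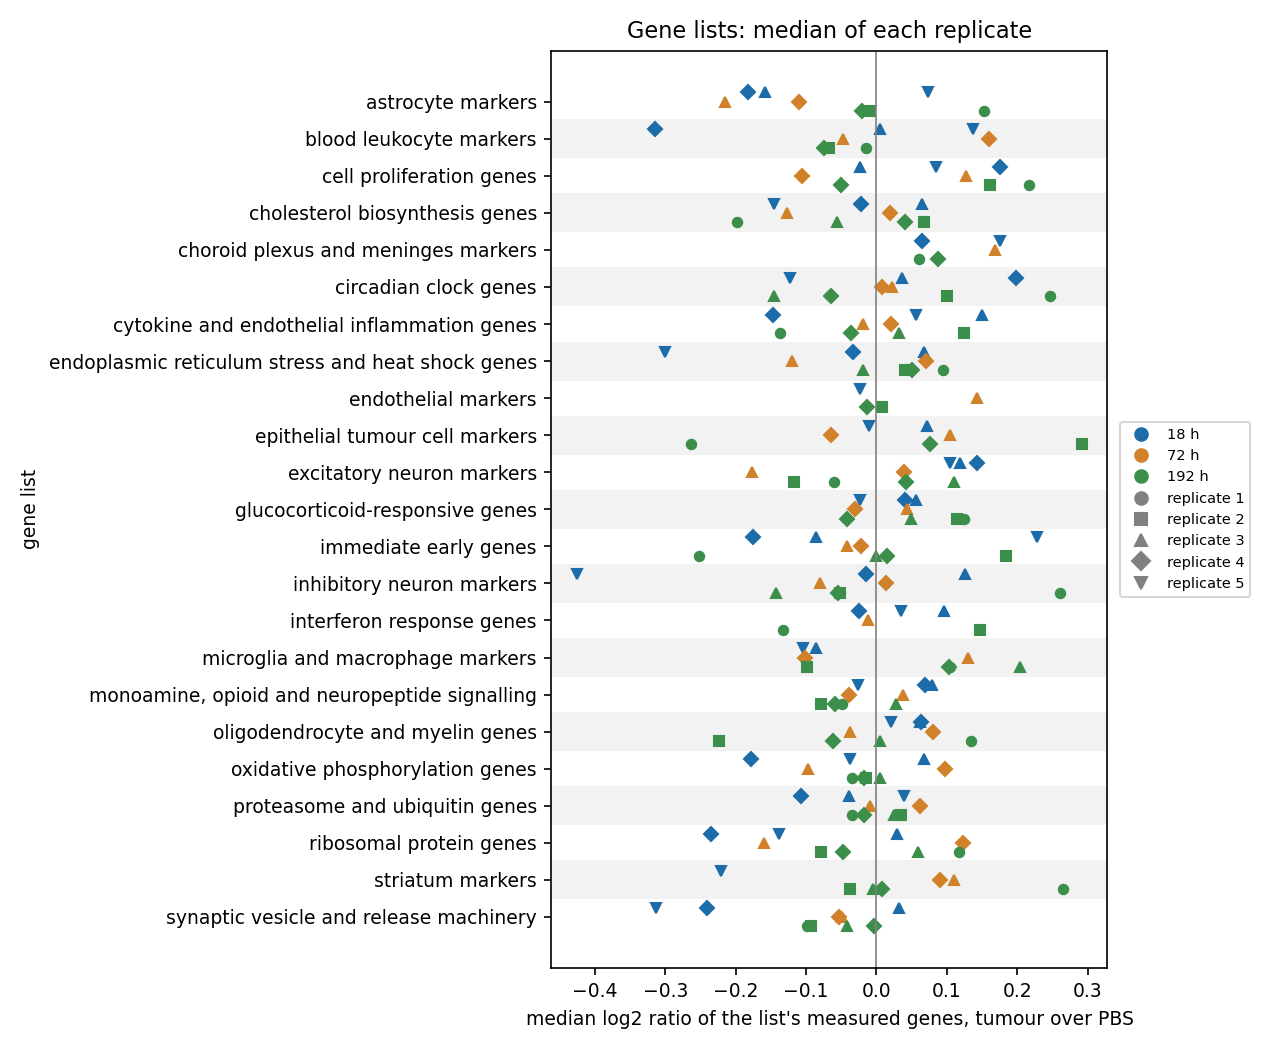
Median log2 ratio of tumour over PBS of the measured genes of each fixed list, with 1 symbol per replicate with at least 4 measured genes, coloured by time (18, 72 and 192 h). For the synaptic vesicle list at 18 h the symbols lie at 0.03, -0.24 and -0.31, and 0 of 66 tests passed.

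The mean of the 3 times asks for a response common to all times. The limma test called 0 of 3171 probes, with 81 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999. Chance alone would give more than 81 if all replicates varied alike. Kif1a, the motor that carries synaptic vesicle precursors along axons, was at -0.24 ± 0.07 and Cmss1 at -0.25 ± 0.07, each lower in 9 of 9 replicates. Nr4a2 was at 0.59 ± 0.17 and higher in 6 of 6 replicates with a value, but its fitted values were 0.50 ± 0.29 at 18 h, 1.74 ± 0.35 at 72 h and -0.46 ± 0.35 at 192 h. The dye covariate puts the 192 h value below both replicates measured then, which gave 0.24 and 0.03. Amer2 was at 0.28 ± 0.08 and higher in 7 of 7. Aanat, an enzyme of melatonin synthesis, was at 0.28 ± 0.08 and Cyb5a, a cytochrome, at 0.67 ± 0.20, each higher in 6 of 7. Smox was at 0.30 ± 0.09 and higher in 6 of 9. Tmem68 was at -0.39 ± 0.10 and lower in 5 of 7, Dapk3 at -0.38 ± 0.10 and lower in 6 of 8, and Mrps36, a mitochondrial protein, at -0.30 ± 0.10 and lower in 6 of 8. Single times stood out for Tmem68 (-0.95) and Mrps36 (-0.61) at 18 h and, at 72 h, for Dapk3 (-1.0), Cyb5a (1.45), Smox (0.74) and Aanat (0.61). At 72 h Cyb5a gave 0.18 in replicate 3 and 2.25 in replicate 4. The adjusted p of each of the 10 was 0.999.

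Differences between times were tested as well. The F test called 0 of 3171 probes, with 88 at an unadjusted p under 0.05. Those are fewer than chance alone would give if all replicates varied alike. Armc1 had the smallest p, at -0.83 ± 0.12 at 18 h, 0.25 ± 0.16 at 72 h and 0.21 ± 0.10 at 192 h (adjusted p = 0.187). Atp6ap2 was at -1.0 ± 0.18, 0.22 ± 0.19 and 0.08 ± 0.12 at these times, and Dbf4 at -0.20 ± 0.12, 0.73 ± 0.16 and -0.05 ± 0.12. Ttll11 was at -0.15 ± 0.15, 1.08 ± 0.23 and -0.15 ± 0.23, and Ttc14 at 0.39 ± 0.25, 0.60 ± 0.28 and -0.54 ± 0.18. The adjusted p of these 4 was 1.00. Pairwise, 0 of 3370 probes differed between 72 and 18 h (87 at an unadjusted p under 0.05), 1 of 4834 between 192 and 18 h (220) and 1 of 4241 between 192 and 72 h (139). The pair of calls were the genes called within a time, Krtap13 (192 minus 18 h, 2.51 ± 0.22, adjusted p = 0.0431) and Spata48 (192 minus 72 h, -3.22 ± 0.27, adjusted p = 0.0271).

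**Figure D3:**
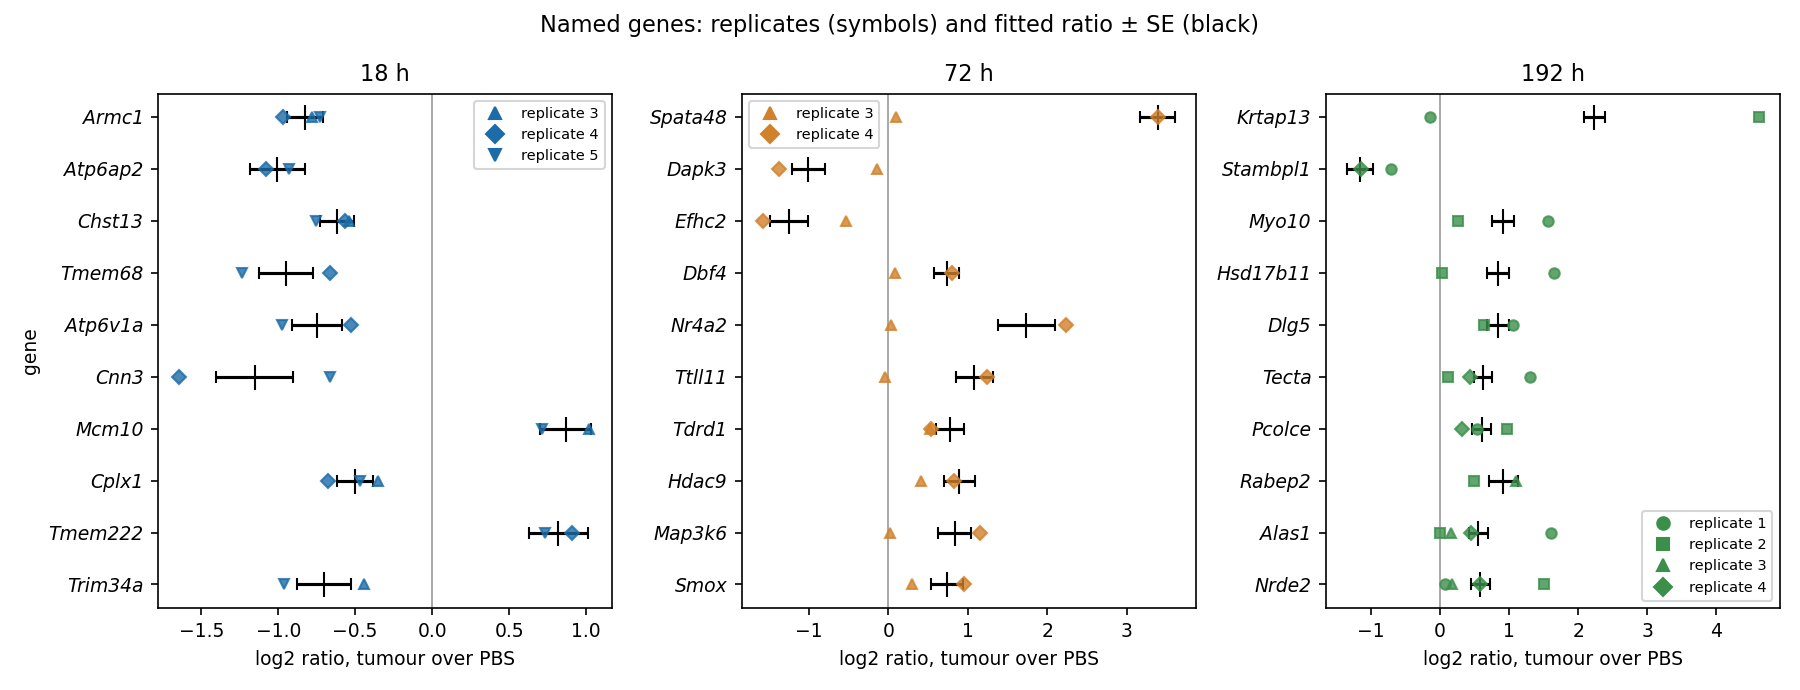
Log2 ratio of tumour over PBS of the named genes at 18, 72 and 192 h, with points for the replicates and bars for the estimate with its standard error. Spata48 has replicate values of 0.10 and 3.39 at 72 h, and Krtap13 has -0.15 and 4.62 at 192 h.

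Of the genes fixed in advance, Fos, an activity marker, was at 0.14 ± 0.19 at 72 h (adjusted p = 0.999) with 1 of 2 replicates higher and at 0.01 ± 0.12 at 192 h (adjusted p = 0.999) with 1 of 4 higher. At 72 h its replicates gave 0.09 and -0.09, both below the fitted value. Its sign turned without loess at 72 h (-0.05) and with sub-grid loess at 192 h (-0.05). Fkbp5, a glucocorticoid target, was at -0.20 ± 0.14 at 18 h (adjusted p = 0.851) with 2 of 3 lower. Serpina3n, an acute phase gene of reactive astrocytes, was at 0.05 ± 0.19 at 18 h, 0.17 ± 0.23 at 72 h and -0.24 ± 0.23 at 192 h (adjusted p of 0.990, 0.999 and 0.999). Its sign turned without loess at 18 h (-0.12) and with the third scanner file alone at 72 h (-0.13). Gfap, Mbp, Ttr, Hbb-b1 and Hba-a1 had 0 named probes on the arrays.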

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

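The tests of whether 1 replicate carries each called gene, the examination of the files behind those genes the splits with an own residual required and the search for signal in 1 channel alone were chosen after the result was seen. The tests of the dye swaps, of 1 array in a swap and of other splits were written before their results.

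Spata48 differed between 192 and 72 h by -3.22 on the log2 scale, and was the gene called at 72 h. Without replicate 4 its ratio at 72 h was 0.10, so 1 replicate carries the call. Within replicate 4 the array with tumour RNA in Cy5 gave -0.32 and the other 7.10, so 1 array of the swap carries it. A spot or dye fault on that array may account for the value, whereas a ratio of the RNA itself, from the animals of replicate 4, would appear on both arrays. On that array the 3 scans gave tumour intensities from 4962230 to 6428710 against 27949 to 56419 for PBS, the latter left after PBS backgrounds of 125123 to 138690 were subtracted.

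Krtap13 differed between 192 and 18 h by 2.51, and was the gene called at 192 h. Without replicate 2 its ratio at 192 h was -0.15, so 1 replicate carries the call. That replicate has 2 arrays, both with tumour RNA in Cy3: on 1 the ratio rests on PBS intensities of 10911 and 29522 over backgrounds of 143184 and 233835, and on the other tumour gave 495680 to 1228000 in the 3 scans with PBS absent or below 0. Tumour signal with weak or no PBS signal appeared on both arrays, which 1 faulty spot would not give. Spata48 also had tumour signal without PBS signal in scans of both arrays, so the pattern is not particular to Krtap13. A dye effect, weak PBS signal or the animals may each account for the value and stay open without a swap. On other arrays Krtap13 gave -0.34 to 0.87 with tumour RNA in Cy3 and -1.51 to -0.07 with tumour RNA in Cy5. No ratio near 4.62 recurred there. Of the 35 splits of the 7 replicates at 18 and 192 h, 6 gave at least as many genes as the real 1, so chance cannot be excluded; the highest other gave 9, and with an own residual required each of the 35 gave 0, so the calls of these splits rest on exact fits.

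After turning to tumour over PBS, the arrays of a dye swap opposed each other, with a median correlation across probes of -0.17 over 6 pairs and 4 pairs below 0. Arrays of different replicates with the same orientation had a median correlation of 0.11 (5 of 55 pairs below 0), and with opposite orientations -0.12 (51 of 58 below 0). Correlations are across probes, which are not independent. A dye effect particular to each probe could give this. With all 16 kept arrays in 1 fit, 52 of 6797 probes passed for the dye. For tumour at 18, 72 and 192 h 0, 5 and 0 passed in that fit, which set no minimum of replicates per time. The 52 point to a dye effect at some probes. The counts cannot be weighed against each other, since the dye coefficient rested on 16 arrays and those of tumour on 6, 3 and 7. A trend across the sub-grids alone is argued against by the correlations of these pairs across spots, with a median of -0.21 with global loess and -0.17 with loess inside each sub-grid (5 of 6 below 0); no biological explanation was tested.

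The median of the astrocyte markers in replicate 1 at 192 h was 0.15, against -0.01, -0.01 and -0.02 in the other 3 (gap over range, 0.929). The median of the striatum markers in the same replicate was 0.26 (0.848). Of 36 groups of 4 replicates tested, 2 had such a gap, and chance gives about 1 in 20.

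In replicate 4 at 72 h, 194 probes had a spot with tumour signal and no PBS signal on both orientations. Independent draws from the counts of its arrays would give 101. The spot need not be the same on both arrays. 0 had the opposite, where such draws would give 0.398. In the other swapped replicates 0 or 1 probe had tumour signal alone and 0 to 5 had PBS signal alone, the 5 where draws would give 19.6. Such draws treat all probes as equally bright on both arrays. The 194 against 101 therefore does not show signal particular to the tumour RNA.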

How the results depend on the processing

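Alternatives with all 23 arrays, array 449 (the array of 72 h replicate 3 left out) kept, 1 dye orientation enough, the third file of array 419 (192 h replicate 3, lowest correlation with another file 0.102) left out, swapped replicates alone, an own residual required, and 72 h alone or poly(A) RNA alone without the dye covariate were chosen after the data were seen.

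At 18 h, 1 gene passed with the print layout as a random block (correlation -0.0818) and 0 in every other alternative, leave-one-out runs included (0 to 0). At 72 h, against 1 gene, 0 passed without background correction, with file 1 or file 2 alone, without the dye covariate, with all arrays in the fit, with RNA type as a block, with total RNA alone, with array 449 kept, without the third file of array 419, with 72 h alone without the dye covariate and with an own residual required. 2 passed with all 23 arrays, 7 without loess and 7 with swapped replicates alone, which rest on replicate 4. Leaving out 1 replicate gave 0 to 9: 9 without 72 h replicate 3 or 4, which leaves a lone replicate assumed to vary like the others, 2 without 192 h replicate 1 or 2, and 0 without 192 h replicate 3 or 4. File 3 alone and the deposited scores gave 1 gene each, 0 shared with the gene called. The 2 genes with all 23 arrays did not include it either. At 192 h, against 1 gene, 0 passed without background correction, with file 2 alone, without the dye covariate, with all arrays in the fit, with RNA type as a block, with total RNA alone, with 192 h fitted alone, with the deposited scores, with all 23 arrays, with 1 orientation enough, with swapped replicates alone, with poly(A) RNA alone without the dye covariate and with an own residual required. Leaving out 1 replicate gave 0 to 1, with 0 without 18 h replicate 3 or 5 or 192 h replicate 1 or 2.

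For the mean of the times, against 0 genes by limma (81 at an unadjusted p under 0.05), 3 passed with all 23 arrays and 1 with swapped replicates alone; leaving out 1 replicate gave 0 to 4 (1 without 72 h replicate 3, 4 without 72 h replicate 4). For differences between times, against 0 (88), 1 passed with the deposited scores, 5 with all 23 arrays and 1 with swapped replicates alone; leaving out 1 replicate gave 0 to 6 (1 without 72 h replicate 3, 6 without 72 h replicate 4). The replicate block gave 1, but the numbers do not pair the samples: 6 pairs of replicates with 1 number had correlations of -0.145 to 0.0144. For gene lists, against 0 of 66, 2 passed without loess (oxidative phosphorylation and ribosomal protein genes, lower at 72 h). With file 3 alone, with all arrays in the fit and with 1 orientation enough, 1 passed each time. All these passes used the preset correlation of 0.01. Leaving out 1 replicate gave 0 to 0.

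Of 1320 values of named genes under alternatives, 22 changed sign without passing on either side, 5 newly passed, 13 no longer passed and 0 reversed a call. The end of a call with an own residual required follows from its construction. For the other changes the cause was not tested. Not run were 72 h alone and poly(A) RNA alone with the dye covariate, which leave no residual, and plain subtraction of background, which is the setting used. No scaling moved the median of all genes by over 0.1. Signal over background of 1.73 to 4.01 limits dim probes.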

Other observations

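The permutation test over all replicates and the sign patterns below were written before their results were seen. The values without the opposite pair and among swapped replicates were chosen afterwards.

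The 2 arrays of replicate 4 at 72 h held 382 and 2386 probes with signal in the tumour channel alone, of 8997. On the array with tumour RNA in Cy3, PBS signal was present at 5256 spots and tumour signal at 9360, and on the other at 8658 and 8333. Gapdh, an enzyme of glycolysis that cells in general express, is among the 194 probes shared, which was looked up after the values were seen. The median signal over background of the shared probes was 1.83 and 1.68.

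A shared response to the tumour at each time would make replicates of 1 time resemble each other more than replicates of different times. The mean correlation across probes was -0.06 within times (10 pairs) and 0.01 between times (26 pairs). An exact permutation test over 1260 assignments gave a one-sided p of 0.970. That test takes no account of dye orientation, and replicates 1 and 2 at 192 h, of opposite orientation, had a correlation of -0.470. Without that pair the mean of the other 9 within times was -0.01. Among the 6 swapped replicates the means were 0.01 within times (4 pairs) and 0.02 between times (11 pairs), with an exact one-sided permutation p of 0.633 over 60 assignments. These values show no excess within times, and at this number of replicates they do not show that none exists.

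For the mean of the 3 times, 100 of 100 sign patterns of the replicates, drawn from 256, gave as many genes as the real 0, and the highest of the others was 0. A real count of 0 fixes this outcome, so it says nothing of chance.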
